A study of Homo sapiens with 12 samples.

How the data were processed

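The deposited tables hold gene-level read counts and, per the file headers, the authors' normalised counts for the same 12 libraries; for genes the deposited values are integers in the count table, and every value of the normalised table, the signal column of each library, equals the count divided by a median-of-ratios size factor within 0.05. Per the submitters' processing notes, libraries were made from polyadenylated RNA with a strand-specific kit and sequenced as paired ends, reads were demultiplexed with bcl2fastq 2.20.0, aligned to hg38 with STAR 2.7.10b, counted with featureCounts 2.0.1 and normalised with DESeq2 1.38.3. The strand setting of the counting, the annotation release and the drug doses are not given in the sources used here. All 12 libraries were matched to a sample, 0 columns were left over, 18 symbols occur more than once and each gene in the table has at least 11 counts in total. Groups of duplicate libraries were looked for and none was found.

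From the counts, genes with low counts were removed by filterByExpr with the 4 groups, libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries in edgeR 4.0.16 (R 4.3.3, limma 3.58.1, robust estimation, 8 residual degrees of freedom). Each of the 6 pairs of groups was tested with the quasi-likelihood F-test, and p values were adjusted by Benjamini-Hochberg over the 17114 genes tested, with a threshold of 0.05. A gene rose or fell when it passed that threshold. Genes shared by the 3 resistant lines are those called in the same direction against sensitive in each. CPM use the TMM-scaled totals, and log2 CPM for the principal components a prior count of 2. A group at 0 counts in all its libraries is given as a bound against 3 counts per library, and a group with 1 to 3 counts as the ratio of mean CPM with its 95% counting interval; these intervals and floors cover counting error only, since no molecular identifiers are described, and such a ratio can move by more than 1.5 times when a library holding counts is left out. The median log2 fold change of all genes lay between -0.005 and 0.001 in the 6 comparisons. Deviations from the group means correlated at 0.151 to 0.337 in the 3 same-numbered pairs of VC-resistant with DT-resistant libraries, all over 0.1, so the data pair these lines by replicate number. The other pairs of groups did not meet that limit, and the fit has no replicate block.

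The comparisons, gene lists and naming rule were set before the data were examined. The 34 gene lists cover ERK-induced and other signalling genes, melanoma cell states, matrix, antigen presentation, interferon, cytokine, cell cycle, apoptosis, metabolism and stress genes, and markers of other cell types. The 33 lists with at least 5 tested members were tested with camera on the edgeR model (inter-gene correlation 0.01, Benjamini-Hochberg over lists within a comparison), and again with a correlation estimated from the residuals. With that estimate, only 2 calls were kept, MAPK output and fibroblast markers in EB-resistant against sensitive. A split mixing the groups called as many lists or more, except in DT-resistant against sensitive, so list calls alone establish no difference. Genes named are the 6 highest and 6 lowest log2 fold changes of each comparison with sensitive (4 and 4 between resistant lines, 6 and 6 shared) among called genes with at least 5 CPM in every library of the higher group, up to 3 members per direction of a list by adjusted p, and NRAS, BRAF, DUSP6, SPRY2, SPRY4, ETV4, ETV5, CCND1, MYC, MITF, AXL, NGFR, EGFR, PDGFRB, IGF1R, WNT5A, B2M, HLA-B, HLA-C, CD274, CDKN1A, MKI67, BCL2L11, ABCB1 and ABCG2. SOX10 and MLANA, also in the rule, have no entry in the table used. Some genes within the rule, and a pattern that involves them, are not reported here. HLA, keratin, zinc finger, olfactory receptor, GSTM, MAGE and SSX genes have near copies, and their counts are uncertain where reads fit more than 1 of them.

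In simulated EB-resistant and sensitive counts (16651 genes), 28, 43 and 50 of 50 genes changed 1.5-, 2- and 4-fold were recovered. The run called 9 unchanged genes. A raised list and a planted region of 40 genes were found. This does not test calls where genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.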

Results

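The libraries measured polyadenylated RNA in WM1366, an NRAS-mutant human melanoma line. In the sensitive parent line, cultured with DMSO, and in 3 daughter lines resistant to a BRAF inhibitor combined with a MEK inhibitor, each group held 3 libraries, 12 in all. The EB-resistant line was kept in encorafenib and binimetinib, the VC-resistant line in vemurafenib and cobimetinib, and the DT-resistant line in dabrafenib and trametinib. The libraries of a group came from 3 independent experiments and carry the replicate numbers 2, 5 and 6. Library totals ran from 40491309 counts (VC-resistant replicate 2) to 54495132 counts (VC-resistant replicate 6). Of 23497 genes in the deposited table, 14663 of them protein-coding, 17114 had enough counts to be tested. The series concerns the action of these drug pairs in NRAS-mutant melanoma and resistance to them. Each resistant line differed from the parent in resistance, in the presence of drug and in its culture history, so a difference cannot be assigned to any 1 of these. Each drug pair has 1 line, so standard errors and adjusted p values measure spread between experiments, not between separately derived lines. A difference between resistant lines cannot be assigned to their drug pairs. Levels are CPM, counts scaled to a common library total, as mean ± SD over a group's 3 libraries. Log2 fold changes (log2FC) carry a standard error back-calculated from the F statistic.

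The VC-resistant and DT-resistant lines resembled each other more closely than any other pair of groups did. Libraries of these lines correlated across genes at a median r of 0.9815, against 0.9314 to 0.9482 for the other 5 pairs of groups (genes are not independent replicates). Each of the 12 libraries lay nearest to a library of its own group. The first 3 principal components held 41.5%, 37.8% and 7.34% of the variance. The 13 mitochondrially encoded mRNAs took 2.11 ± 0.587% of counts in sensitive, 1.80 ± 0.546% in EB-resistant, 1.58 ± 0.256% in VC-resistant and 1.36 ± 0.287% in DT-resistant libraries. The 83 ribosomal protein genes took 5.60 ± 0.121%, 5.91 ± 0.283%, 7.89 ± 0.255% and 6.88 ± 0.224% in the same order. The 20 most abundant genes took 7.82 ± 0.411%, 7.88 ± 0.124%, 9.19 ± 0.715% and 9.14 ± 0.543%, and the 55 histone genes 0.1012 ± 0.00597%, 0.1094 ± 0.0046%, 0.0574 ± 0.00456% and 0.0628 ± 0.00317%. For 3 libraries against 3 the smallest p of a two-sided exact permutation test is 0.1, so none of the 36 quality tests between libraries could pass 0.05.

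**Figure D1:**
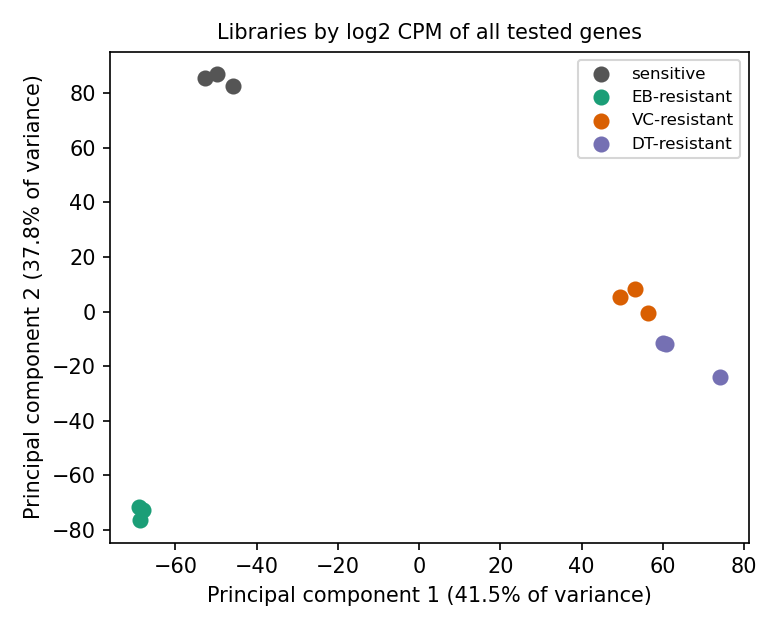
Principal components of log2 CPM, with the first component (41.5% of the variance) on the horizontal axis and the second (37.8%) on the vertical axis; each point is 1 library, coloured by group. The 3 libraries of each group lie together, with the VC-resistant and DT-resistant libraries next to each other and apart from the sensitive and EB-resistant libraries, and 1 DT-resistant library farther out than its group.

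EB-resistant cells were compared with sensitive cells to see what changed in the line resistant to encorafenib and binimetinib. Transcripts that ERK signalling induces were lower. DUSP6, which encodes a phosphatase that inactivates ERK, fell from 107 ± 5.91 to 5.63 ± 0.798 CPM (log2FC -4.24 ± 0.19, adjusted p = 1.17e-09). SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, fell from 50.3 ± 6.15 to 0.936 ± 0.469 CPM (log2FC -5.75 ± 0.31, adjusted p = 2.94e-08). ETV4 and ETV1, ETS-family transcription factors, fell as well (log2FC -3.77 ± 0.097 and -4.35 ± 0.16, adjusted p = 7.98e-13 and 2.26e-11). CCND1, which encodes cyclin D1, fell from 421 ± 23.5 to 37.6 ± 8.03 CPM (log2FC -3.49 ± 0.13, adjusted p = 3.21e-11). EPHA4, an ephrin receptor in the same list, rose (log2FC 1.03 ± 0.12, adjusted p = 2.45e-06). Of 22 MAPK output genes tested, 1 rose and 18 fell (1 and 20 adjusted over the list alone). The MAPK output list had a median log2FC of -1.78 (camera adjusted p = 1.11e-19, adjusted p = 0.026 with an estimated correlation). NRAS, the mutated oncogene of this line, stood at 377 ± 13.4 and 390.0 ± 6.12 CPM, with no call (log2FC 0.05 ± 0.059, adjusted p = 0.487), and BRAF at 31.5 ± 3.64 and 28.8 ± 1.74 CPM (log2FC -0.13 ± 0.12, adjusted p = 0.356).

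**Figure D2:**
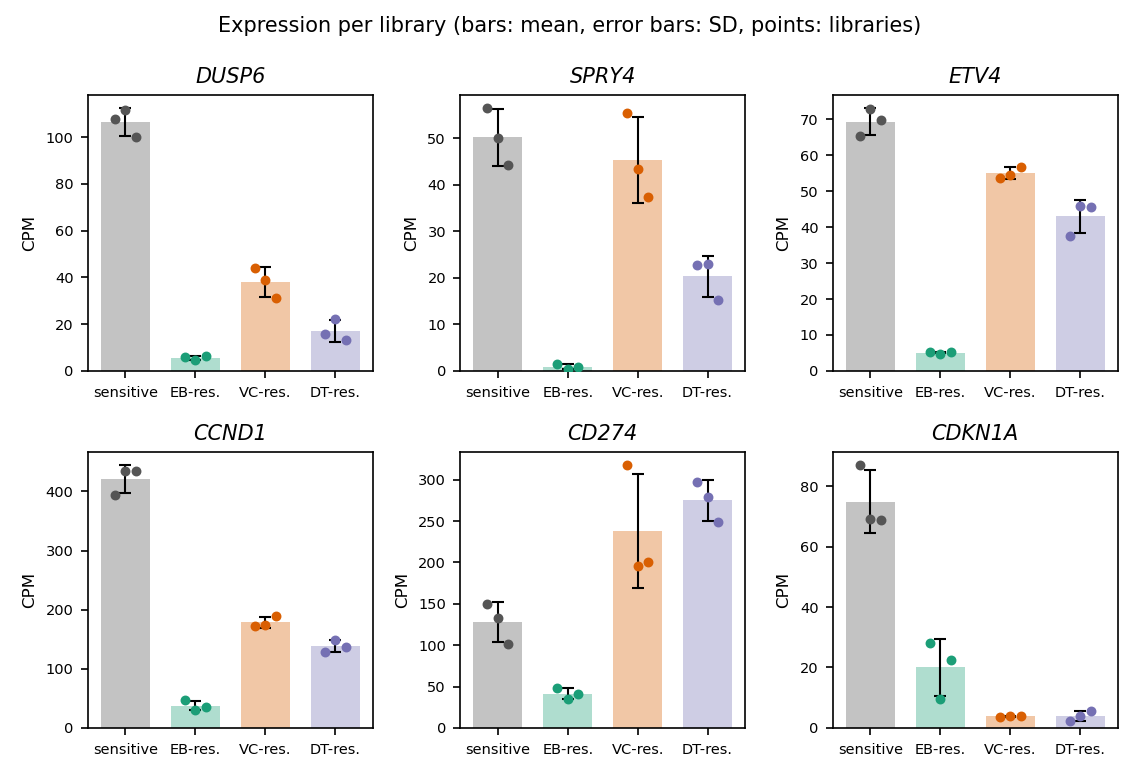
CPM of DUSP6, SPRY4, ETV4, CCND1, CD274 and CDKN1A in the 4 groups, on a vertical axis starting at 0 in each panel; bars are means, error bars SD and points the 3 libraries of a group. DUSP6 averages 107 CPM in sensitive and 5.63 CPM in EB-resistant libraries, and CDKN1A 74.9 CPM in sensitive and 3.94 CPM in DT-resistant libraries.

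In total 4869 genes rose and 4730 fell, 56.1% of those tested, and of these 2132 rose and 1489 fell by at least 2-fold. MEGF6 was at 0 counts in every sensitive library and at 25.3 ± 5.697 CPM in EB-resistant libraries, at least 400-fold higher. TFAP2B, a neural crest transcription factor, was at least 271-fold higher (17.2 ± 1.66 CPM), DAPK1, a death-associated protein kinase, at least 125-fold higher (7.92 ± 2.36 CPM) and TRIM29 at least 114-fold higher (7.22 ± 0.945 CPM), each from 0 counts. SULF1, a sulfatase that edits heparan sulfate, reached 34.8 ± 7.27 CPM (ratio 4800, counting interval 862 to 190000), and CNN1, a smooth muscle calponin, 28.2 ± 3.78 CPM (ratio 1940, counting interval 537 to 16000). In the other direction, ESM1, which encodes the proteoglycan endocan, went from 114 ± 13.96 CPM to a total of 1 count in 3 libraries (ratio 16500, counting interval 2950 to 650000). GTSF1, a germline factor of the piRNA pathway, was at 18.2 ± 1.43 CPM in sensitive cells and at 0 counts here, at least 293-fold lower. The long noncoding RNA UCA1 was at least 149-fold lower and ASTN1, a neuronal adhesion protein gene, at least 89.8-fold lower. BCL2A1, an anti-apoptotic BCL2 relative, was also lower (ratio 1330, counting interval 367 to 11000). MMP1, the interstitial collagenase, fell from 2298 ± 223 to 2.32 ± 0.857 CPM (log2FC -9.95 ± 0.70, adjusted p = 2.28e-06).

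Fibroblast marker genes rose in EB-resistant cells. Of 7 fibroblast marker genes tested, 6 rose and 0 fell (the same adjusted over the list alone). The fibroblast marker list had a median log2FC of 4.13 (camera adjusted p = 7.67e-07, adjusted p = 0.0163 with an estimated correlation). PDGFRB, a receptor for platelet-derived growth factor, rose from 0.784 ± 0.156 to 74.5 ± 11.97 CPM (log2FC 6.57 ± 0.18, adjusted p = 1.42e-12). THY1, a surface glycoprotein, rose from 127 ± 19.4 to 409.5 ± 20.5 CPM (log2FC 1.69 ± 0.096, adjusted p = 1.57e-09). COL1A1, a type I collagen chain, rose from 0.325 ± 0.0593 to 17.9 ± 4.26 CPM (log2FC 5.78 ± 0.56, adjusted p = 4.99e-06). Of 30 collagen and matrix genes tested, 14 rose and 9 fell (14 and 10 adjusted over the list alone, camera adjusted p = 0.234). Of 27 cytokines and chemokines tested, 11 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.191). CCL2, a monocyte chemoattractant, rose from 0.03499 ± 0.0116 to 11.4 ± 3.28 CPM (log2FC 8.23 ± 0.39, adjusted p = 2.34e-10), while the inflammatory cytokine IL1B fell from 746 ± 130.4 to 3.12 ± 1.87 CPM (log2FC -7.90 ± 0.70, adjusted p = 1.23e-05), with a log2FC of -8.49 without EB-resistant replicate 2. AXL and NGFR, markers of dedifferentiated melanoma, fell (log2FC -0.82 ± 0.083 and -4.22 ± 0.43, adjusted p = 7.43e-07 and 7.32e-07), with NGFR at 2 CPM in its top library. MITF, a melanocyte lineage factor, was not called (log2FC 0.18 ± 0.094, adjusted p = 0.121), but was without sensitive replicate 6 (log2FC 0.26, adjusted p = 0.0435).

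Genes of the type I interferon response rose, while MHC class II genes fell. Of 37 interferon-response genes tested, 27 rose and 2 fell (28 and 2 adjusted over the list alone). The interferon list had a median log2FC of 0.91 (camera adjusted p = 2.88e-05, adjusted p = 0.658 with an estimated correlation). SAMD9L and IFIT1, antiviral effectors, rose (log2FC 1.72 ± 0.12 and 1.82 ± 0.15, adjusted p = 9.51e-09 and 1.04e-07). Of 9 MHC class II genes tested, 1 rose and 6 fell (the same adjusted over the list alone). The class II list had a median log2FC of -1.82 (camera adjusted p = 0.0474, adjusted p = 0.658 with an estimated correlation). CTSS, the protease cathepsin S, fell from 28.5 ± 1.61 to 9.96 ± 0.764 CPM (log2FC -1.51 ± 0.10, adjusted p = 1.11e-08), HLA-DRA fell (log2FC -5.10 ± 0.45, adjusted p = 1.64e-07) and HLA-DMA rose (log2FC 1.30 ± 0.18, adjusted p = 1.65e-05). The class II call was lost without sensitive replicate 2 (adjusted p = 0.0601), sensitive replicate 6 (0.056), EB-resistant replicate 5 (0.0531) or 6 (0.0637), or VC-resistant replicate 2 (0.0695) or 6 (0.0533). Of 22 MHC class I genes tested, 11 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.191). CD274, which encodes PD-L1, fell from 128 ± 24.2 to 41.6 ± 6.58 CPM (log2FC -1.62 ± 0.21, adjusted p = 5.46e-05). Of 24 checkpoint and co-stimulatory ligands tested, 12 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.14).

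Glycolysis and cell cycle genes fell, and cholesterol synthesis and drug metabolism genes rose. Of 26 glycolysis genes tested, 1 rose and 18 fell (1 and 19 adjusted over the list alone). The glycolysis list had a median log2FC of -0.49 (camera adjusted p = 0.000159, adjusted p = 0.209 with an estimated correlation). PFKP, a phosphofructokinase, fell from 475 ± 20.2 to 257 ± 8.14 CPM (log2FC -0.89 ± 0.061, adjusted p = 1.33e-08). Of 24 cholesterol synthesis genes tested, 14 rose and 2 fell (15 and 2 adjusted over the list alone). The cholesterol synthesis list had a median log2FC of 0.53 (camera adjusted p = 0.0331, adjusted p = 0.796 with an estimated correlation). SC5D and LSS rose (log2FC 2.22 ± 0.14 and 1.06 ± 0.12, adjusted p = 1.24e-08 and 3.32e-06). The cholesterol synthesis call was lost without sensitive replicate 2 (adjusted p = 0.07). Of 22 drug metabolism genes tested, 13 rose and 4 fell (the same adjusted over the list alone). The drug metabolism list had a median log2FC of 0.79 (camera adjusted p = 0.0474, adjusted p = 0.658 with an estimated correlation). NQO1, a quinone reductase, rose from 82.4 ± 5.26 to 337 ± 27.7 CPM (log2FC 2.03 ± 0.10, adjusted p = 3.14e-10). The drug metabolism call held without EB-resistant replicate 2 or VC-resistant replicate 5 and was lost without any 1 of the other 10 libraries (adjusted p from 0.0583 to 0.0937). Of 49 cell cycle genes tested, 2 rose and 27 fell (2 and 28 adjusted over the list alone). The cell cycle list had a median log2FC of -0.40 (camera adjusted p = 0.00433, adjusted p = 0.796 with an estimated correlation). AURKB, a mitotic kinase, and CDK1 were lower (log2FC -0.87 ± 0.079 and -0.81 ± 0.079, adjusted p = 2.55e-07 and 4.48e-07). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, fell from 74.9 ± 10.4 to 20.02 ± 9.48 CPM (log2FC -1.90 ± 0.36, adjusted p = 0.00138).

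VC-resistant cells were compared with sensitive cells to see what changed in the line resistant to vemurafenib and cobimetinib. RASGRP3, a RAS exchange factor, rose from 0.414 ± 0.109 to 6.495 ± 0.631 CPM (log2FC 3.96 ± 0.26, adjusted p = 1.49e-08). Several transcripts induced by ERK were lower. DUSP6 fell from 107 ± 5.91 to 38.1 ± 6.43 CPM (log2FC -1.49 ± 0.17, adjusted p = 8.3e-06), and CCND1 fell from 421 ± 23.5 to 178 ± 9.92 CPM (log2FC -1.24 ± 0.12, adjusted p = 8.02e-07). SPRY4 was not called (50.3 ± 6.15 and 45.4 ± 9.21 CPM, log2FC -0.15 ± 0.23, adjusted p = 0.605), and SPRY1 rose (log2FC 0.80 ± 0.29, adjusted p = 0.0281), a call lost without sensitive replicate 5 or 6 or VC-resistant replicate 2 (adjusted p from 0.0944 to 0.122). Of 22 MAPK output genes tested, 1 rose and 12 fell (the same adjusted over the list alone). The MAPK output list had a median log2FC of -0.34 (camera adjusted p = 0.00319, adjusted p = 0.685 with an estimated correlation). NRAS was not called (log2FC -0.03 ± 0.059, adjusted p = 0.638). BRAF rose from 31.5 ± 3.64 to 46.3 ± 2.02 CPM (log2FC 0.56 ± 0.11, adjusted p = 0.000746).

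In total 4717 genes rose and 4694 fell, 55% of those tested, of which 1649 rose and 1579 fell by at least 2-fold. NR5A1, the steroidogenic factor 1 gene, reached 13.2 ± 1.03 CPM (ratio 1820, counting interval 326 to 71700). PCDH18, a protocadherin, rose from 0.114 ± 0.0526 to 25.2 ± 1.24 CPM (log2FC 7.77 ± 0.26, adjusted p = 1.21e-11). CD36, a fatty acid and thrombospondin receptor, rose from 0.121 ± 0.0484 to 15.5 ± 1.72 CPM (log2FC 6.99 ± 0.24, adjusted p = 1.21e-11). TAGLN, an actin-binding protein of smooth muscle, rose from 0.391 ± 0.114 to 70.9 ± 16.1 CPM (log2FC 7.48 ± 0.22, adjusted p = 4.24e-12). The potassium channel subunit gene KCNE4 also rose (log2FC 6.52 ± 0.32, adjusted p = 5.26e-09), and the zinc finger gene ZNF626 reached 7.06 ± 0.747 CPM from 0.0284 ± 0.0335 CPM (adjusted p = 5.68e-10, log2FC 9.08 without sensitive replicate 2 and 7.84 with it). NTSR1, the neurotensin receptor gene, was lower (18.5 ± 6.93 CPM in sensitive cells, ratio 1360, counting interval 378 to 11300), as were IL13RA2, a decoy receptor for interleukin 13 (ratio 792, counting interval 271 to 3840), TMEM163, a zinc transporter gene (ratio 350, counting interval 120 to 1700), and F2RL3, a thrombin receptor gene (ratio 321, counting interval 110 to 1560). ESM1 fell from 114 ± 13.96 to 0.115 ± 0.0378 CPM (log2FC -9.91 ± 0.20, adjusted p = 9.57e-13). ADGRG1, an adhesion receptor, fell from 49.8 ± 9.19 to 0.228 ± 0.103 CPM (log2FC -7.81 ± 0.26, adjusted p = 1.21e-11).

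Genes of MHC class I presentation and of the interferon response rose in VC-resistant cells, and MHC class II genes fell. Of 22 class I genes tested, 15 rose and 0 fell (the same adjusted over the list alone). The class I list had a median log2FC of 0.69 (camera adjusted p = 0.00291, adjusted p = 0.685 with an estimated correlation). ERAP1, a peptide-trimming aminopeptidase, rose from 85.5 ± 2.64 to 186 ± 8.63 CPM (log2FC 1.13 ± 0.084, adjusted p = 5.77e-08). Of 37 interferon-response genes tested, 25 rose and 2 fell (26 and 2 adjusted over the list alone). The interferon list had a median log2FC of 1.06 (camera adjusted p = 7.02e-05, adjusted p = 0.685 with an estimated correlation). IFIT2 and IFIT1 were higher (log2FC 2.01 ± 0.14 and 1.999 ± 0.15, adjusted p = 2.2e-08 and 8.14e-08). Of 9 class II genes tested, 0 rose and 8 fell (0 and 9 adjusted over the list alone). The class II list had a median log2FC of -2.22 (camera adjusted p = 0.00319, adjusted p = 0.685 with an estimated correlation). CIITA, the class II transactivator, fell (log2FC -3.57 ± 0.38, adjusted p = 1.89e-06). HLA-DRA fell from 2.93 ± 0.722 to 0.436 ± 0.207 CPM (log2FC -2.76 ± 0.35, adjusted p = 1.18e-05). CD274 rose from 128 ± 24.2 to 238 ± 69.02 CPM (log2FC 0.89 ± 0.20, adjusted p = 0.00324). Of 24 checkpoint and co-stimulatory ligands tested, 9 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.403). Of 27 cytokines and chemokines tested, 11 rose and 6 fell (11 and 7 adjusted over the list alone, camera adjusted p = 0.204). IL32, an inflammatory cytokine, rose from 3.52 ± 0.289 to 43.1 ± 11.3 CPM (log2FC 3.61 ± 0.20, adjusted p = 2.19e-08).

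Unfolded protein response and oxidative phosphorylation genes rose, and cell cycle genes fell. Of 30 unfolded protein response genes tested, 18 rose and 3 fell (19 and 3 adjusted over the list alone). The unfolded protein response list had a median log2FC of 0.49 (camera adjusted p = 0.00962, adjusted p = 0.685 with an estimated correlation). HYOU1, a chaperone, rose from 346 ± 29.7 to 791 ± 98.1 CPM (log2FC 1.19 ± 0.11, adjusted p = 4.23e-07). EIF2AK3, the stress-sensing kinase PERK, rose from 17.1 ± 1.62 to 32.4 ± 0.788 CPM (log2FC 0.92 ± 0.093, adjusted p = 1.12e-06). CHAC1, a target of ATF4 in the same stress response, fell from 6.08 ± 1.18 to 2.05 ± 0.364 CPM (log2FC -1.57 ± 0.22, adjusted p = 2.32e-05). Of 47 oxidative phosphorylation genes tested, 24 rose and 6 fell (the same adjusted over the list alone). The oxidative phosphorylation list had a median log2FC of 0.22 (camera adjusted p = 0.0369, adjusted p = 0.792 with an estimated correlation). UQCRC2, a complex III subunit, and PPARGC1A, a coactivator of mitochondrial biogenesis, rose (log2FC 0.92 ± 0.073 and 1.84 ± 0.18, adjusted p = 1.03e-07 and 6.66e-07), and TFAM, the mitochondrial transcription factor, fell (log2FC -0.98 ± 0.10, adjusted p = 1.39e-06). The oxidative phosphorylation call was lost without sensitive replicate 2 (adjusted p = 0.106) or VC-resistant replicate 6 (0.068). Of 49 cell cycle genes tested, 0 rose and 24 fell (the same adjusted over the list alone). The cell cycle list had a median log2FC of -0.36 (camera adjusted p = 0.0255, adjusted p = 0.867 with an estimated correlation). The mitotic kinesin KIF11 and the kinase PLK1 were lower (log2FC -0.64 ± 0.10 and -0.53 ± 0.088, adjusted p = 6.86e-05 and 0.000133). Without sensitive replicate 6 the cell cycle call was lost (adjusted p = 0.0753). CDKN1A fell from 74.9 ± 10.4 to 3.83 ± 0.204 CPM (log2FC -4.29 ± 0.41, adjusted p = 1.8e-05). Of 7 fibroblast markers tested, 4 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.0803). PDGFRB rose from 0.784 ± 0.156 to 2.598 ± 0.311 CPM (log2FC 1.72 ± 0.19, adjusted p = 3.32e-06).

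DT-resistant cells were compared with sensitive cells to see what changed in the line resistant to dabrafenib and trametinib. RASGRP3 rose from 0.414 ± 0.109 to 4.79 ± 1.41 CPM (log2FC 3.52 ± 0.26, adjusted p = 3.66e-08). ERK-induced transcripts were lower. DUSP6 fell from 107 ± 5.91 to 17.1 ± 4.54 CPM (log2FC -2.64 ± 0.17, adjusted p = 5.87e-08), SPRY4 fell from 50.3 ± 6.15 to 20.3 ± 4.47 CPM (log2FC -1.30 ± 0.23, adjusted p = 0.000499) and CCND1 fell from 421 ± 23.5 to 138 ± 10.1 CPM (log2FC -1.61 ± 0.12, adjusted p = 5e-08). EMP1 and PHLDA1 fell (log2FC -1.47 ± 0.10 and -1.87 ± 0.13, adjusted p = 2.1e-08 and 3.6e-08), and MAFF, a small MAF transcription factor gene, rose (log2FC 1.09 ± 0.26, adjusted p = 0.00469). Of 22 MAPK output genes tested, 1 rose and 16 fell (the same adjusted over the list alone). The MAPK output list had a median log2FC of -0.73 (camera adjusted p = 3.11e-06, adjusted p = 0.268 with an estimated correlation). NRAS rose to 418 ± 8.57 CPM (log2FC 0.15 ± 0.059, adjusted p = 0.0379), a call lost without sensitive replicate 2 or 6 or DT-resistant replicate 2 or 5 (adjusted p from 0.0614 to 0.115), and BRAF rose from 31.5 ± 3.64 to 46.5 ± 8.12 CPM (log2FC 0.56 ± 0.11, adjusted p = 0.000591).

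In total 5106 genes rose and 5010 fell, 59.1% of those tested, of which 1963 rose and 1810 fell by at least 2-fold. From 0 counts in sensitive cells, UBE2QL1 reached 27.7 ± 10.3 CPM, at least 438-fold higher, and COL6A6, a type VI collagen chain, 8.004 ± 2.78 CPM, at least 126-fold higher. ACKR3, an atypical receptor for the chemokine CXCL12, reached 23.4 ± 11.1 CPM (ratio 3230, counting interval 580 to 128000), and NR5A1 11.2 ± 3.45 CPM (ratio 1540, counting interval 276 to 60700). KRT17, a keratin, rose from 0.0924 ± 0.0358 to 95.7 ± 56.8 CPM (log2FC 9.99 ± 0.85, adjusted p = 7.94e-06), with a log2FC of 9.39 without DT-resistant replicate 2. OR2T8, an olfactory receptor gene, rose from 0.04096 ± 0.0398 to 30.7 ± 3.34 CPM (log2FC 9.42 ± 0.37, adjusted p = 6.84e-11), with a log2FC of 10.30 without sensitive replicate 5. ESM1 was at 0 counts, at least 1720-fold lower. FSTL5 (ratio 2990, counting interval 1020 to 14500), NTSR1 (ratio 2610, counting interval 468 to 103000), TMEM163 (ratio 1180, counting interval 213 to 46800) and BEX1 (ratio 714, counting interval 244 to 3460) were lower. SPNS2, a transporter of sphingosine 1-phosphate, fell from 30.01 ± 4.37 to 0.0664 ± 0.0958 CPM (log2FC -8.77 ± 0.41, adjusted p = 1.25e-09), with a log2FC of -8.17 without DT-resistant replicate 2 and -11.09 without replicate 5.

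MHC class I, interferon and cytokine genes rose in DT-resistant cells. Of 22 MHC class I genes tested, 19 rose and 0 fell (21 and 0 adjusted over the list alone). The class I list had a median log2FC of 1.06 (camera adjusted p = 6.91e-09, adjusted p = 0.48 with an estimated correlation). ERAP1 rose from 85.5 ± 2.64 to 268 ± 34.9 CPM (log2FC 1.65 ± 0.085, adjusted p = 9.29e-10). B2M, the class I light chain, rose from 617 ± 30.7 to 1548 ± 459 CPM (log2FC 1.33 ± 0.15, adjusted p = 1.05e-05). HLA-B rose (log2FC 1.98 ± 0.27, adjusted p = 4.85e-05). Of 37 interferon-response genes tested, 34 rose and 1 fell (the same adjusted over the list alone). The interferon list had a median log2FC of 1.51 (camera adjusted p = 1.55e-11, adjusted p = 0.48 with an estimated correlation). EPSTI1 and IFIT1 were higher (log2FC 4.11 ± 0.23 and 1.80 ± 0.15, adjusted p = 1.82e-08 and 1.53e-07). B2M, HLA-B and EPSTI1 were highest in DT-resistant replicate 2, at 2078, 34.4 and 63.06 CPM, against 1278 and 1288, 18.07 and 19.07, and 34.09 and 33.86 CPM in replicates 5 and 6. The class I and interferon calls held without any 1 library (adjusted p at most 1.59e-07 and 9.26e-10). Of 27 cytokines and chemokines tested, 14 rose and 2 fell (the same adjusted over the list alone). The cytokine list had a median log2FC of 1.07 (camera adjusted p = 0.00136, adjusted p = 0.268 with an estimated correlation). IL32 rose from 3.52 ± 0.289 to 122 ± 25.1 CPM (log2FC 5.11 ± 0.20, adjusted p = 1.17e-09), and IL1B fell from 746 ± 130.4 to 109 ± 66.1 CPM (log2FC -2.78 ± 0.54, adjusted p = 0.00184). CD274 rose from 128 ± 24.2 to 275 ± 24.6 CPM (log2FC 1.10 ± 0.20, adjusted p = 0.000761). Of 24 checkpoint and co-stimulatory ligands tested, 12 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.0571). Of 9 class II genes tested, 2 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.468).

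Collagen and matrix genes and unfolded protein response genes rose, and cell cycle genes fell. Of 30 collagen and matrix genes tested, 16 rose and 5 fell (16 and 6 adjusted over the list alone). The matrix list had a median log2FC of 0.70 (camera adjusted p = 0.018, adjusted p = 0.641 with an estimated correlation). FBN1 rose from 59.4 ± 0.732 to 399.9 ± 20.6 CPM (log2FC 2.75 ± 0.083, adjusted p = 2.44e-12), COL15A1 rose (log2FC 4.24 ± 0.23, adjusted p = 6.06e-09) and MMP1 fell from 2298 ± 223 to 63.3 ± 35.3 CPM (log2FC -5.18 ± 0.55, adjusted p = 3.95e-05). Of 7 fibroblast markers tested, 5 rose and 0 fell (the same adjusted over the list alone). The fibroblast marker list had a median log2FC of 1.67 (camera adjusted p = 0.0289, adjusted p = 0.268 with an estimated correlation). PDGFRB rose to 2.49 ± 0.410 CPM (log2FC 1.67 ± 0.20, adjusted p = 3.54e-06). Of 30 unfolded protein response genes tested, 19 rose and 3 fell (21 and 4 adjusted over the list alone). The unfolded protein response list had a median log2FC of 0.87 (camera adjusted p = 2.53e-05, adjusted p = 0.495 with an estimated correlation). EIF2AK3 and HYOU1 were higher (log2FC 1.25 ± 0.093 and 1.22 ± 0.11, adjusted p = 3.83e-08 and 2.53e-07) and CHAC1 was lower (log2FC -0.97 ± 0.21, adjusted p = 0.000989). Of 49 cell cycle genes tested, 1 rose and 34 fell (1 and 35 adjusted over the list alone). The cell cycle list had a median log2FC of -0.47 (camera adjusted p = 0.000695, adjusted p = 0.911 with an estimated correlation). BIRC5, which encodes survivin, fell from 140.1 ± 17.8 to 89.6 ± 8.08 CPM (log2FC -0.64 ± 0.089, adjusted p = 2e-05). CDKN1A fell from 74.9 ± 10.4 to 3.94 ± 1.57 CPM (log2FC -4.25 ± 0.41, adjusted p = 1.48e-05). IGF1R, a growth factor receptor, rose from 37.9 ± 3.38 to 74.7 ± 11.7 CPM (log2FC 0.98 ± 0.11, adjusted p = 2.67e-06).

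**Figure D3:**
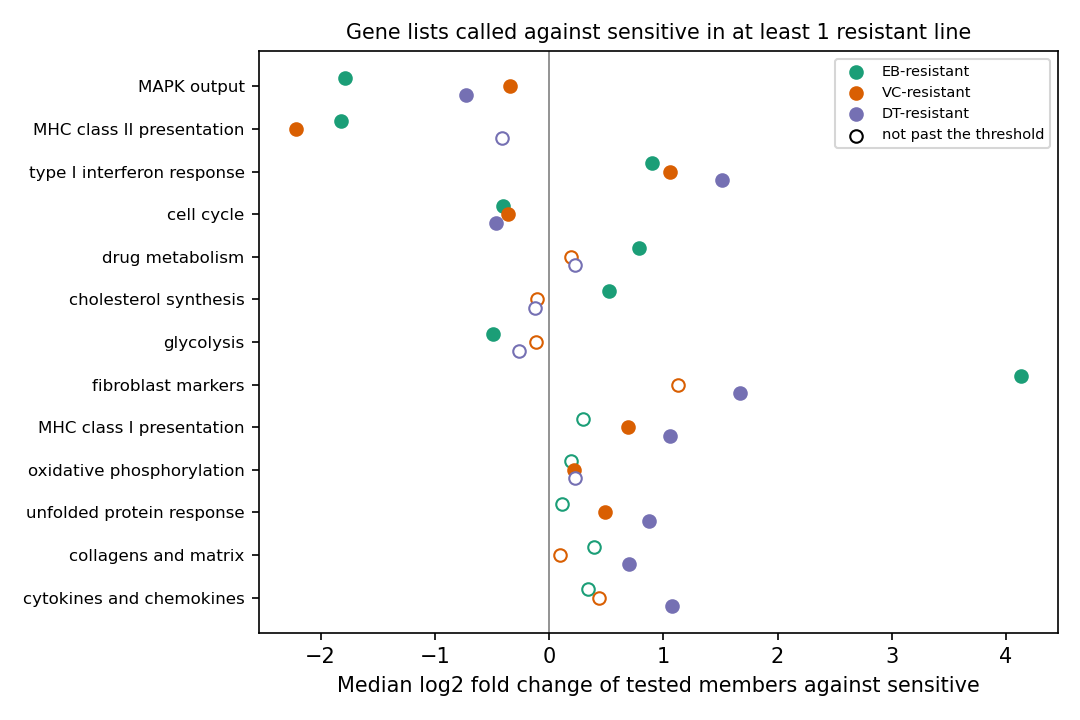
Median log2 fold change against sensitive of the tested members of the 13 gene lists called in at least 1 resistant line, on the horizontal axis, by line; filled points are lists past camera adjusted p < 0.05 and open points are not. MAPK output genes lie below 0 in each line, at -1.78 in EB-resistant, -0.34 in VC-resistant and -0.73 in DT-resistant cells.

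Other signalling lists held members moving both ways in each line and were not called. Of the 24 RAS, RAF, MEK and ERK component genes tested, 9, 7 and 9 rose and 11, 6 and 7 fell in the EB, VC and DT lines (9, 7 and 10 and, for the falls, 12, 6 and 9 adjusted over the list alone, camera adjusted p = 0.695, 0.0803 and 0.111). MAP2K1, which encodes MEK1, fell from 83.7 ± 4.27 to 38.1 ± 1.79 CPM (log2FC -1.14 ± 0.066, adjusted p = 1.92e-09) in EB-resistant cells. Of the 21 PI3K, AKT and mTOR component genes tested, 6, 8 and 10 rose and 5, 4 and 4 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.574, 0.712 and 0.468). Of the 27 receptor tyrosine kinases tested, 15, 9 and 10 rose and 10, 9 and 8 fell in the EB, VC and DT lines (15, 10 and 10 and, for the falls, 10, 9 and 9 adjusted over the list alone, camera adjusted p = 0.257, 0.956 and 0.778). KIT rose in EB-resistant cells (log2FC 3.67 ± 0.21, adjusted p = 8e-09). Of the 27 receptor tyrosine kinase ligands tested, 12, 11 and 11 rose and 11, 6 and 8 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.52, 0.175 and 0.468). Of the 41 TGF-beta, WNT and BMP pathway genes tested, 15, 12 and 15 rose and 19, 21 and 18 fell in the EB, VC and DT lines (15, 13 and 16 and, for the falls, 19, 22 and 19 adjusted over the list alone, camera adjusted p = 0.842, 0.644 and 0.721).

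Lists of melanoma cell states were not called in any line against sensitive. Of the 14 melanocyte differentiation genes tested, 2, 5 and 5 rose and 5, 6 and 5 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.52, 0.849 and 0.929). GPNMB, a melanosomal glycoprotein, rose in all 3 lines, from 21.7 ± 2.102 to 183 ± 17.96, 174 ± 11.5 and 168 ± 26.6 CPM (adjusted p = 3.83e-11, 1.04e-10 and 7.56e-11). Of the 14 neural crest-like genes tested, 7, 3 and 5 rose and 5, 6 and 5 fell in the EB, VC and DT lines (7, 3 and 5 and, for the falls, 5, 7 and 5 adjusted over the list alone, camera adjusted p = 0.621, 0.0803 and 0.459). SOX9, a neural crest transcription factor, fell from 86.8 ± 9.71 to 7.81 ± 0.248 CPM (log2FC -3.47 ± 0.19, adjusted p = 7.08e-09) in EB-resistant cells. With genes at 0 set to their bound, the neural crest-like median in the VC-resistant line was 0.00, against -0.51 from the fitted values. Of the 32 undifferentiated or invasive state genes tested, 11, 10 and 12 rose and 15, 16 and 12 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.11, 0.0803 and 0.881). PLAU, the urokinase gene, fell from 1089 ± 42.9 to 193 ± 16.9 CPM (log2FC -2.50 ± 0.12, adjusted p = 4.04e-10) in EB-resistant cells, and WNT5A stood at 91.4 ± 2.48, 64.9 ± 15.3, 64.8 ± 6.99 and 262 ± 35.2 CPM in sensitive, EB-, VC- and DT-resistant cells. Of the 22 YAP and TEAD target genes tested, 8, 7 and 6 rose and 9, 6 and 6 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.861, 0.849 and 0.982). Of the 22 EMT regulator and adhesion genes tested, 6, 6 and 9 rose and 9, 11 and 10 fell in the EB, VC and DT lines (6, 6 and 10 and, for the falls, 9, 11 and 10 adjusted over the list alone, camera adjusted p = 0.28, 0.644 and 0.881).

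A shared set of genes changed in the same direction in all 3 resistant lines. PCDH18 rose from 0.114 ± 0.0526 CPM to 26.02 ± 5.802, 25.2 ± 1.24 and 29.4 ± 3.61 CPM in EB-, VC- and DT-resistant cells (log2FC 7.82 ± 0.26, 7.77 ± 0.26 and 7.997 ± 0.26, adjusted p = 7.67e-12, 1.21e-11 and 6.5e-12). CD36 (log2FC 6.73 ± 0.24, 6.99 ± 0.24 and 5.79 ± 0.24), KCNE4 (8.32 ± 0.32, 6.52 ± 0.32 and 6.38 ± 0.33), the guanylate cyclase subunit gene GUCY1A2 (6.03 ± 0.29, 5.98 ± 0.29 and 5.75 ± 0.29), FGF13 (5.67 ± 0.16, 5.64 ± 0.16 and 5.87 ± 0.16) and the mechanosensitive channel gene PIEZO2 (7.04 ± 0.29, 5.61 ± 0.30 and 6.38 ± 0.30) also rose in each. HAS2, a hyaluronan synthase, fell from 16.6 ± 1.69 CPM to 0.173 ± 0.115, 0.102 ± 0.162 and 0.0513 ± 0.0109 CPM, and MMP1 from 2298 ± 223 CPM to 2.32 ± 0.857, 73.5 ± 31.8 and 63.3 ± 35.3 CPM. SPNS2, NTSR1, TMEM163 and ESM1 were lower in each line as well. In all, 2141 genes rose in each line, 722 of them by at least 2-fold in each, and 2072 fell in each, 519 of them by at least 2-fold. A further 1601 genes were called higher in 1 line and lower in another, and 3168 were called in no line.

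The VC-resistant and DT-resistant responses overlapped most. In these lines 3913 genes rose in both and 3868 fell in both, where independent lists of these sizes would share 1407 and 1374, and 84 genes went opposite ways. For the EB- and VC-resistant lines 2378 genes rose in both (1342 by the same product) and 2329 fell in both (1297), with 1277 opposite. For the EB- and DT-resistant lines these were 2696 (1453), 2608 (1385) and 1151. Across genes the log2 fold changes correlated at r = 0.884 for VC and DT, 0.558 for EB and DT and 0.526 for EB and VC. The 3 comparisons share the sensitive libraries, which were not divided between them. In 20 simulations of unchanged groups with shared controls, mean r lay from 0.497 to 0.5 and same-sign genes from 66.5% to 66.6%. The real shares were 64.9% for EB and VC, 67.5% for EB and DT and 85.8% for VC and DT. With a mean of 0.1 genes called in a pair's first line, 0 called in both was set in advance. So was a simulated covariance (0.0305 to 0.0306) under the real 1.01, 1.21 and 1.67 in that order. Neither measures the overlap that shared controls give lines that do differ.

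EB-resistant cells were compared directly with VC-resistant cells to see where lines resistant to different drug pairs differ. ERK-induced transcripts were lower in EB-resistant cells, with CCND1 at 37.6 ± 8.03 CPM in EB-resistant and 178 ± 9.92 CPM in VC-resistant libraries (log2FC -2.25 ± 0.12, adjusted p = 2.99e-09). ETV4 and ETV1 were lower too (log2FC -3.44 ± 0.096 and -4.16 ± 0.16, adjusted p = 1.31e-12 and 7.1e-11). Of 22 MAPK output genes tested, 2 were higher and 18 lower (2 and 19 adjusted over the list alone). The MAPK output list had a median log2FC of -0.97 (camera adjusted p = 5.39e-11, adjusted p = 0.108 with an estimated correlation). MAP2K1 was lower in EB-resistant cells (log2FC -1.18 ± 0.066, adjusted p = 2.52e-09). Of 24 RAS, RAF, MEK and ERK component genes tested, 3 were higher and 11 lower (the same adjusted over the list alone). The RAS and RAF component list had a median log2FC of -0.15 (camera adjusted p = 0.0339, adjusted p = 0.26 with an estimated correlation). That call held without EB-resistant replicate 2 and was lost without any 1 of the other 11 libraries (adjusted p from 0.0659 to 0.0954).

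In total 5070 genes were higher and 4921 lower in EB-resistant than in VC-resistant cells, 58.4% of those tested, 2173 and 1525 by at least 2-fold. From 0 counts in VC-resistant cells, TFAP2B was at least 257-fold, SGCE, a sarcoglycan, at least 201-fold and SLC17A9, a vesicular nucleotide transporter, at least 91-fold higher in EB-resistant cells. VSIR, which encodes the checkpoint ligand VISTA, stood at 12.5 ± 0.616 CPM (ratio 1430, counting interval 257 to 56600). At 0 counts in EB-resistant cells, GTSF1 was at least 774-fold, UCA1 at least 262-fold and ASTN1 at least 120-fold lower, and NR5A1 was lower (ratio 1940, counting interval 348 to 76700). Of 7 fibroblast markers tested, 6 were higher and 0 lower (the same adjusted over the list alone). The fibroblast marker list had a median log2FC of 1.77 (camera adjusted p = 0.000432, adjusted p = 0.0954 with an estimated correlation). PDGFRB was higher (log2FC 4.85 ± 0.16, adjusted p = 1.34e-11). Of 14 neural crest-like genes tested, 8 were higher and 2 lower (8 and 3 adjusted over the list alone). The neural crest-like list had a median log2FC of 0.52 (camera adjusted p = 0.0339, adjusted p = 0.834 with an estimated correlation). That call was lost without VC-resistant replicate 5 (adjusted p = 0.0752) or 6 (0.0929). Of 24 cholesterol synthesis genes tested, 13 were higher and 0 lower (the same adjusted over the list alone). The cholesterol synthesis list had a median log2FC of 0.56 (camera adjusted p = 0.00573, adjusted p = 0.86 with an estimated correlation). LSS was higher (log2FC 1.66 ± 0.12, adjusted p = 5.06e-08). Of 30 unfolded protein response genes tested, 4 were higher and 21 lower (the same adjusted over the list alone). The unfolded protein response list had a median log2FC of -0.45 (camera adjusted p = 0.0339, adjusted p = 0.86 with an estimated correlation). PDIA4 was lower (log2FC -1.29 ± 0.11, adjusted p = 2.51e-07). The unfolded protein response call was lost without VC-resistant replicate 2 (adjusted p = 0.0547).

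EB-resistant cells were compared with DT-resistant cells for the same purpose. MHC class I and interferon-response genes were lower in EB-resistant cells, and CCND1 stood at 37.6 ± 8.03 CPM in EB-resistant and 138 ± 10.1 CPM in DT-resistant libraries (log2FC -1.88 ± 0.12, adjusted p = 1.54e-08). Of 22 MAPK output genes tested, 3 were higher and 16 lower (the same adjusted over the list alone). The MAPK output list had a median log2FC of -0.72 (camera adjusted p = 2.17e-06, adjusted p = 0.291 with an estimated correlation). FOSL1, an AP-1 transcription factor gene, was higher (log2FC 0.62 ± 0.14, adjusted p = 0.002). Of 22 class I genes tested, 0 were higher and 17 lower (the same adjusted over the list alone). The class I list had a median log2FC of -0.78 (camera adjusted p = 2.75e-05, adjusted p = 0.548 with an estimated correlation). ERAP1 and ERAP2 were lower (log2FC -1.22 ± 0.084 and -1.17 ± 0.081, adjusted p = 1.99e-08 and 2.18e-08). Of 37 interferon-response genes tested, 3 were higher and 21 lower (3 and 22 adjusted over the list alone). The interferon list had a median log2FC of -0.65 (camera adjusted p = 0.0265, adjusted p = 0.714 with an estimated correlation). RSAD2, which encodes viperin, was lower (log2FC -6.38 ± 0.59, adjusted p = 4.56e-07; log2FC -7.05 without EB-resistant replicate 6). The interferon call was lost without EB-resistant replicate 5 (adjusted p = 0.0602) or 6 (0.051). CD274 stood at 41.6 ± 6.58 CPM in EB-resistant and 275 ± 24.6 CPM in DT-resistant libraries (log2FC -2.73 ± 0.21, adjusted p = 1.5e-06), and the cytokine IL6 at 64.2 ± 14.5 CPM in EB-resistant and 883 ± 279 CPM in DT-resistant libraries (log2FC -3.78 ± 0.34, adjusted p = 1.06e-05).

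In total 4865 genes were higher and 4922 lower in EB-resistant than in DT-resistant cells, 57.2% of those tested, 2047 and 1526 by at least 2-fold. From 0 counts in DT-resistant cells, TFAP2B was at least 259-fold, VSIR at least 189-fold, PNMA8A at least 171-fold and COX7A1, a cytochrome c oxidase subunit gene, at least 162-fold higher in EB-resistant cells. GTSF1 was at least 665-fold and ASTN1 at least 148-fold lower, and UBE2QL1 (ratio 3990, counting interval 716 to 158000) and NR5A1 (ratio 1640, counting interval 295 to 64900) were lower. MAP2K1 was lower (log2FC -1.13 ± 0.066, adjusted p = 4.02e-09). Of 24 RAS, RAF, MEK and ERK component genes tested, 3 were higher and 8 lower (the same adjusted over the list alone). The RAS and RAF component list had a median log2FC of -0.10 (camera adjusted p = 0.0237, adjusted p = 0.291 with an estimated correlation). That call held without sensitive replicate 2, EB-resistant replicate 2 or DT-resistant replicate 6 and was lost without any 1 of the other 9 libraries (adjusted p from 0.051 to 0.0814). Of 24 cholesterol synthesis genes tested, 13 were higher and 0 lower (the same adjusted over the list alone). The cholesterol synthesis list had a median log2FC of 0.62 (camera adjusted p = 0.000221, adjusted p = 0.616 with an estimated correlation). LSS was higher (log2FC 1.53 ± 0.12, adjusted p = 1.19e-07). Of 30 unfolded protein response genes tested, 1 was higher and 19 lower (the same adjusted over the list alone). The unfolded protein response list had a median log2FC of -0.69 (camera adjusted p = 2.75e-05, adjusted p = 0.548 with an estimated correlation). PDIA4 was lower (log2FC -1.56 ± 0.11, adjusted p = 4.67e-08). Of 7 fibroblast markers tested, 4 were higher and 1 lower (the same adjusted over the list alone). The fibroblast marker list had a median log2FC of 0.96 (camera adjusted p = 0.00455, adjusted p = 0.274 with an estimated correlation). PDGFRB was higher (log2FC 4.90 ± 0.16, adjusted p = 9.06e-12) and LUM, which encodes lumican, was lower (log2FC -1.54 ± 0.43, adjusted p = 0.0134), a call lost without DT-resistant replicate 2 (adjusted p = 0.0578).

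VC-resistant cells were compared with DT-resistant cells, the most similar pair. Antigen presentation, interferon and cytokine genes were lower and ERK-induced genes higher in VC-resistant cells. DUSP6 stood at 38.1 ± 6.43 CPM in VC-resistant and 17.1 ± 4.54 CPM in DT-resistant libraries (log2FC 1.15 ± 0.17, adjusted p = 0.000481), and FOSL1 and PHLDA1 were higher (log2FC 1.26 ± 0.14 and 0.86 ± 0.12, adjusted p = 5.34e-05 and 0.00029), while IER3 was lower (log2FC -1.54 ± 0.13, adjusted p = 2.42e-06). Of 22 MAPK output genes tested, 12 were higher and 2 lower (13 and 2 adjusted over the list alone). The MAPK output list had a median log2FC of 0.36 (camera adjusted p = 0.000113, adjusted p = 0.276 with an estimated correlation). Of 22 MHC class I genes tested, 0 were higher and 15 lower (0 and 18 adjusted over the list alone). The class I list had a median log2FC of -0.52 (camera adjusted p = 7.81e-09, adjusted p = 0.331 with an estimated correlation). The peptide transporter gene TAP1 was lower (log2FC -0.76 ± 0.12, adjusted p = 0.000742). Of 9 class II genes tested, 0 were higher and 6 lower (the same adjusted over the list alone). The class II list had a median log2FC of -1.75 (camera adjusted p = 1.66e-05, adjusted p = 0.255 with an estimated correlation). CTSS was lower (log2FC -1.12 ± 0.10, adjusted p = 2.89e-06). Of 37 interferon-response genes tested, 1 was higher and 24 lower (1 and 27 adjusted over the list alone). The interferon list had a median log2FC of -0.66 (camera adjusted p = 1.86e-10, adjusted p = 0.344 with an estimated correlation). IRF7, an interferon regulatory factor, was lower (log2FC -1.27 ± 0.17, adjusted p = 0.000134). Of 27 cytokines and chemokines tested, 0 were higher and 14 lower (1 and 18 adjusted over the list alone). The cytokine list had a median log2FC of -0.94 (camera adjusted p = 1.87e-06, adjusted p = 0.077 with an estimated correlation). IL6 stood at 201 ± 19.8 CPM in VC-resistant and 883 ± 279 CPM in DT-resistant libraries (log2FC -2.14 ± 0.32, adjusted p = 0.00172). Of 24 checkpoint and co-stimulatory ligands tested, 2 were higher and 8 lower (2 and 10 adjusted over the list alone). The checkpoint ligand list had a median log2FC of -0.26 (camera adjusted p = 0.014, adjusted p = 0.306 with an estimated correlation). CD24 was lower (log2FC -2.73 ± 0.25, adjusted p = 3.19e-05). The checkpoint call was lost without DT-resistant replicate 2 (adjusted p = 0.0671).

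In total 1211 genes were higher and 1491 lower in VC-resistant than in DT-resistant cells, 15.8% of those tested, 312 and 481 by at least 2-fold. Without VC-resistant replicate 6 these counts were 756 and 966. Higher in VC-resistant cells were CAVIN2, a component of caveolae (log2FC 5.69 ± 0.59, adjusted p = 0.000213), PPP2R2B, a subunit of protein phosphatase 2A (log2FC 4.11 ± 0.20, adjusted p = 5.62e-09), SNCAIP (log2FC 3.39 ± 0.25, adjusted p = 4.52e-07) and OXTR, the oxytocin receptor (log2FC 3.35 ± 0.29, adjusted p = 4.13e-05). OR2T8 (log2FC -6.55 ± 0.28, adjusted p = 5.14e-09), KRT17 (log2FC -5.51 ± 0.59, adjusted p = 0.000276), COL6A6 (log2FC -4.77 ± 0.56, adjusted p = 0.000316) and the potassium channel gene KCNJ15 (log2FC -4.63 ± 0.26, adjusted p = 2.11e-08) were lower. The value of KRT17 was -6.36 without VC-resistant replicate 2 and -4.90 without DT-resistant replicate 2, and that of COL6A6 -5.81 without VC-resistant replicate 2. WNT5A, a ligand of noncanonical WNT signalling, stood at 64.8 ± 6.99 CPM in VC-resistant and 262 ± 35.2 CPM in DT-resistant libraries (log2FC -2.02 ± 0.15, adjusted p = 3e-06).

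Matrix and signalling lists also differed between the VC-resistant and DT-resistant lines. Of 30 collagen and matrix genes tested, 3 were higher and 15 lower (4 and 16 adjusted over the list alone). The matrix list had a median log2FC of -0.55 (camera adjusted p = 0.000194, adjusted p = 0.331 with an estimated correlation). FBN1 and the protease MMP2 were lower (log2FC -1.06 ± 0.079 and -2.92 ± 0.36, adjusted p = 5.13e-07 and 0.000614). Of 32 undifferentiated or invasive state genes tested, 3 were higher and 11 lower (the same adjusted over the list alone). The invasive state list had a median log2FC of -0.09 (camera adjusted p = 0.000587, adjusted p = 0.077 with an estimated correlation). INHBA, an activin subunit, was lower (log2FC -2.25 ± 0.16, adjusted p = 2.31e-06). Of 30 unfolded protein response genes tested, 0 were higher and 11 lower (0 and 12 adjusted over the list alone). The unfolded protein response list had a median log2FC of -0.27 (camera adjusted p = 0.000469, adjusted p = 0.518 with an estimated correlation). HERPUD1 was lower (log2FC -1.33 ± 0.18, adjusted p = 0.000397). Of 41 TGF-beta, WNT and BMP pathway genes tested, 8 were higher and 12 lower (10 and 18 adjusted over the list alone). The TGF-beta, WNT and BMP list had a median log2FC of -0.18 (camera adjusted p = 0.00454, adjusted p = 0.163 with an estimated correlation). LEF1, a WNT effector, was higher (log2FC 1.27 ± 0.17, adjusted p = 0.000152) and TGFBR1, a TGF-beta receptor, stood at 974 ± 102 CPM in VC-resistant and 2260 ± 210.0 CPM in DT-resistant libraries (log2FC -1.21 ± 0.088, adjusted p = 3.95e-07). Without VC-resistant replicate 2 the call of this list was lost (adjusted p = 0.0846). Of 49 cell cycle genes tested, 4 were higher and 0 lower (2 and 0 adjusted over the list alone). The cell cycle list had a median log2FC of 0.19 (camera adjusted p = 0.0155, adjusted p = 0.701 with an estimated correlation). FOXM1, a mitotic transcription factor, was higher (log2FC 0.40 ± 0.10, adjusted p = 0.0174), a call lost without VC-resistant replicate 5 or 6 or DT-resistant replicate 2 (adjusted p from 0.0539 to 0.0759). The cell cycle call was lost without VC-resistant replicate 6 (adjusted p = 0.0592) or DT-resistant replicate 2 (0.576).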

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

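No test in this part was chosen after its result was seen. Of the genes that the naming rule gives by the size of their change or by symbol, its list members not included, 12 were higher than sensitive in 1 resistant line and lower in another, with the lines also differing when compared directly (edgeR quasi-likelihood, adjusted p < 0.05), in 22 such comparisons. CD274, the PD-L1 gene, fell in EB-resistant cells and rose in the others, with log2 fold changes of -2.73 between EB-resistant and DT-resistant cells and -2.52 between EB-resistant and VC-resistant cells. The checkpoint ligand gene VSIR rose in EB-resistant cells and fell in the other lines, and was at least 189-fold higher in EB-resistant than in DT-resistant cells and higher by a ratio of 1430 (counting interval 257 to 56600) against VC-resistant cells. WNT5A rose in DT-resistant cells alone and fell in both other lines, with log2 fold changes of -2.01 for EB-resistant and -2.02 for VC-resistant against DT-resistant cells. CAVIN2 fell in DT-resistant cells and rose in both others (log2 fold changes 6.38 for EB-resistant and 5.69 for VC-resistant against DT-resistant cells). The potassium channel gene KCNJ15 fell in VC-resistant and rose in DT-resistant cells (log2 fold change -4.63).

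The other 7 genes set EB-resistant cells against the VC-resistant or DT-resistant line. GTSF1 fell in EB-resistant cells and rose in the others, and was at least 665-fold lower than in DT-resistant and at least 774-fold lower than in VC-resistant cells. ASTN1 was at least 148-fold lower than in DT-resistant cells. BEX1 was higher by a ratio of 2030 (counting interval 693 to 9830) in EB-resistant than in DT-resistant cells, with a log2 fold change of 6.80 against VC-resistant cells (8.34 without VC-resistant replicate 2). COX7A1 was at least 162-fold higher than in DT-resistant cells, with a log2 fold change of 8.09 against VC-resistant cells that rests on 5 counts, all in VC-resistant replicate 2, so that it is only a bound without that library (7.41 without VC-resistant replicate 6). PNMA8A was at least 171-fold higher than in DT-resistant cells, with a log2 fold change of 7.22 against VC-resistant cells (8.96 without VC-resistant replicate 2). SGCE was higher by a ratio of 1840 (counting interval 329 to 72500) in EB-resistant than in DT-resistant cells and at least 201-fold higher than in VC-resistant cells. SLC17A9 was at least 91.7-fold higher than in DT-resistant and at least 91-fold higher than in VC-resistant cells. No explanation was tested for these genes.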

How the results depend on the processing

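No alternative in this part was chosen after the results were seen. For 20 counts of genes or lists, 356 alternative values were computed, and 341 lay within 1.5 times the reported count. Counts of genes stayed within that range under DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, a filter of 1 CPM in at least 3 libraries, only the compared groups in the fit, limma-trend on log2 normalised counts and a block for replicate number. Libraries with the same number correlated in their deviations at a median of 0.0712 over 18 pairs (0.00144 to 0.337, 4 over 0.1), against -0.0405 for 36 differently numbered pairs, and 10 of the 12 libraries correlated best on average with their own number, a hint of pairing from the data and not the design. With the replicate block, VC-resistant against DT-resistant gave 1591 higher and 1923 lower, and EB-, VC- and DT-resistant against sensitive 5117 and 5014, 4962 and 4989, and 5313 and 5272. For VC-resistant against DT-resistant the block changed 1 list call, ABC transporters (camera adjusted p = 0.0445, from 0.0538). In DT-resistant against sensitive it added checkpoint ligands (0.0168, from 0.0571) and glycolysis (0.0385, from 0.0703). With the block, MHC class II (0.0615, from 0.0474) and drug metabolism (0.113, from 0.0474) in EB-resistant cells, oxidative phosphorylation (0.0501, from 0.0369) in VC-resistant cells, and RAS and RAF components (0.0658, from 0.0339) and the neural crest-like state (0.079, from 0.0339) in EB against VC were not called. It changed no other call of a list or of a gene named. When each library was left out in turn, the genes higher in VC-resistant than in DT-resistant cells numbered 756 to 1306 and those lower 966 to 1596, both lowest without VC-resistant replicate 6; fewer libraries leave less power, and the cause was not tested further. The lists called in EB-resistant against sensitive numbered 5 (without sensitive replicate 2) to 8, and in VC-resistant against sensitive 6 to 11 (without VC-resistant replicate 2); the cause was not tested. With an estimated correlation 2, 0, 0, 0, 0 and 0 lists were called in EB, VC and DT against sensitive, EB against VC, EB against DT and VC against DT; the cause was not tested. With fry, which asks whether genes of a list move and not whether they move more than others, 26, 21, 22, 19 and 23 lists were called in the first 5 of these. Of the genes named, the uncalled values of BCL2L11 in EB-resistant and NRAS in VC-resistant cells turned sign, to 0.0307 without EB-resistant replicate 2 and 0.0061 without VC-resistant replicate 5, and ran from -0.3926 to 0.0307 and from -0.0634 to 0.0061 over the left-out libraries; the cause was not tested. Depth limits statements on genes near the floor of 3 counts per library, such as ABCB1.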

Other observations

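The test of the shared sensitive libraries was chosen after the result it bears on had been seen. The BCL2 family, p53 target, ABC transporter and immediate early gene lists were not called against sensitive. Of the 17 BCL2 family genes tested, 4, 3 and 4 rose and 6, 9 and 9 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.0968, 0.301 and 0.207). PMAIP1, which encodes the pro-apoptotic protein NOXA, fell from 166 ± 2.39 to 53.8 ± 4.41 CPM (log2FC -1.62 ± 0.071, adjusted p = 1.04e-10) in EB-resistant cells, and BCL2L11, which encodes BIM, was called in no line (log2 fold changes -0.17 ± 0.17, 0.09 ± 0.17 and -0.13 ± 0.17, adjusted p = 0.429, 0.689 and 0.547). Of the 27 p53 target and CDK inhibitor genes tested, 10, 4 and 7 rose and 10, 8 and 5 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.574, 0.656 and 0.997). FAS, a death receptor, fell in all 3 lines (log2 fold changes -1.50 ± 0.28, -1.79 ± 0.29 and -2.18 ± 0.30, adjusted p = 0.000341, 0.000105 and 1.82e-05). Of the 14 ABC transporter genes tested, 6, 5 and 7 rose and 4, 5 and 4 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.217, 0.528 and 0.925). ABCC2, a conjugate exporter, rose from 3.72 ± 0.479 to 38.6 ± 2.12 CPM (log2FC 3.37 ± 0.16, adjusted p = 1.99e-10) in EB-resistant cells, and ABCG2 stood at 11.5 ± 3.54, 6.43 ± 1.15, 3.95 ± 0.703 and 15.6 ± 2.45 CPM in sensitive, EB-, VC- and DT-resistant cells. ABCB1, at 0.391 ± 0.143 CPM in sensitive cells, was at 0 counts in each resistant line, at least 5.85-fold lower. Of the 21 immediate early genes tested, 7, 8 and 8 rose and 3, 5 and 6 fell in the EB, VC and DT lines (7, 8 and 9 and, for the falls, 3, 5 and 6 adjusted over the list alone, camera adjusted p = 0.697, 0.656 and 0.81).

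PRAME, a melanoma antigen gene, rose in all 3 lines, from 10.2 ± 0.234 to 38.8 ± 1.85, 41.03 ± 2.62 and 34.1 ± 5.11 CPM (adjusted p = 8.89e-10, 1.36e-09 and 4.29e-09). Of the 17 cancer-testis and melanoma antigen genes tested, 6, 5 and 5 rose and 0, 5 and 6 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.0968, 0.378 and 0.881). Of the 16 NK cell ligand and death receptor genes tested, 3, 4 and 7 rose and 9, 5 and 4 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.422, 0.956 and 0.778). Of the marker lists of other cell types, only the fibroblast list was called against sensitive. Of the 6 epithelial markers tested, 1, 1 and 1 rose and 2, 2 and 2 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.695, 0.528 and 0.699). Of the 8 endothelial markers tested, 2, 3 and 1 rose and 2, 4 and 3 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.697, 0.416 and 0.278). Of the 9 Schwann cell or neuronal markers tested, 3, 2 and 2 rose and 3, 2 and 3 fell in the EB, VC and DT lines (the same numbers adjusted over the list alone, camera adjusted p = 0.935, 0.956 and 0.81). Of the 4 haematopoietic markers tested, 1, 0 and 2 rose and 1, 1 and 2 fell in the EB, VC and DT lines (2, 0 and 2 and, for the falls, 1, 1 and 2 adjusted over the list alone). The last list had too few members for a test.

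The median and mean log2 fold change and the direction of the camera test were not all of 1 sign for some uncalled lists, given here as median, mean and test direction. In EB-resistant cells these were EMT genes (-0.22, 0.08, down), RAS, RAF, MEK and ERK components (-0.19, 0.07, down), endothelial markers (-0.13, 0.73, down), p53 targets (-0.12, 0.15, up), receptor tyrosine kinase ligands (0.13, -0.30, up) and unfolded protein response (0.11, -0.03, up). In VC-resistant cells these were NK cell ligands (-0.07, -0.14, up), RAS, RAF, MEK and ERK components (-0.02, 0.48, up), YAP and TEAD targets (-0.03, 0.11, up), cancer-testis antigens (-0.08, 0.17, up), drug metabolism (0.19, -0.09, up), epithelial markers (0.07, -0.05, down), haematopoietic markers (0.30, -0.35, no test), melanocyte differentiation (0.17, -0.06, up) and receptor tyrosine kinases (0.10, -0.23, down). In DT-resistant cells these were ABC transporters (0.38, -0.36, up), EMT genes (0.20, 0.12, down), RAS, RAF, MEK and ERK components (-0.03, 0.45, up), TGF-beta, WNT and BMP genes (-0.06, 0.14, up), YAP and TEAD targets (0.02, 0.06, down), cancer-testis antigens (-0.16, 0.01, up), epithelial markers (-0.17, 0.01, down), haematopoietic markers (0.17, -0.20, no test), melanocyte differentiation (0.12, -0.08, down), p53 targets (-0.14, -0.31, up) and receptor tyrosine kinase ligands (0.20, -0.07, up).

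A scan of windows of 15 neighbouring genes, over 9814 expressed genes, called 2 stretches of the short arm of chromosome 2 lower in each resistant line. These were 264140 to 20225433 and 45388680 to 55112621 in EB-, 663877 to 20051628 and 38561969 to 55419895 in VC-, and 8852690 to 20225433 and 38481851 to 55112621 in DT-resistant cells. The scan also called a stretch of chromosome 12 lower (75480753 to 84913629, median -1.176) and 1 of chromosome 3 higher (127672935 to 131502983, median 0.837) in EB-resistant cells, and 1 of chromosome 5 higher (148383935 to 150701077, median 0.761) in DT-resistant cells. From the first to the last gene called on the short arm of chromosome 2 in all 3 lines (8852690 to 55112621, genes between the stretches included), 95 of 138 expressed genes fell in all 3 resistant lines and 2 rose in all 3, with medians of -0.976, -0.584 and -0.588 in EB-, VC- and DT-resistant cells. The share of genes called lower there was 93.5%, 75.4% and 74.6%, against 34.9%, 31% and 32.5% of the 9814 expressed genes. The region was set by low fold changes of these same genes, so these counts and shares describe it and do not test it. Gene length is argued against, since the highest of the 3 medians stayed at -0.62 against genes of the same length class. The 77 low genes of the region, not looked at when the pattern was noticed, had medians of at most -0.71. Any cause acting on the region predicts this, and DNA was not measured. Lower copy number in the resistant lines, culture history and drug are not separated and remain open.

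VC-resistant and DT-resistant cells resembled each other more than either resembled EB-resistant cells. The shared sensitive libraries are argued against as the source, since in fits to the 6 libraries compared, which hold none of them, the direct comparison called 0.202 times as many genes as the fewer of the comparisons with EB-resistant cells (0.276 times in the fit to all 12 libraries). Libraries filed under the wrong one of the 2 lines are argued against, as 0 of the 6 libraries lay nearest to a library of the other line. A common resistant ancestor, carry-over of cells between the cultures and similar effects of the drug pairs stay open.

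Other ways of dividing the libraries were run for each count. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison the other splits called 0 genes, so 1 of the 10 reached the real counts given above. Lists called were 8, 7, 8, 6, 7 and 11 in the order of the results. The highest other split called 9, 9, 7, 6, 7 and 12. Of 10 splits, 2, 3, 1, 2, 6 and 3 reached the real number. For the genes shared by the 3 resistant lines, 1 of 100 splits, the real one, reached the real counts. These were 2141 higher (highest other 1392) and 2072 lower (highest other 1257). Nearly all other splits put libraries of different lines into 1 group, which widens the spread within groups. The real split is then favoured whether or not the lines share a response, so no conclusion on the sharing is drawn from it.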
